A study of Drosophila melanogaster with 6 samples.

How the data were processed

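Total RNA of fly heads had been hybridised to Affymetrix DrosGenome1 arrays, per the file headers of the array description files. The label of wild type 1 names an ENZO labelling kit and an Agilent scanner, and the other labels name neither. The deposited values are intensity values per probe set, on a linear scale without a stated summary method, background correction or normalization, which are not given in the sources used here. They are positive, and between 56 and 75 probe sets per array lie above 65535, the highest value of a 16-bit scan. The highest value of an array lay between 2.14e+06 and 2.89e+06, which argues against plain scan intensities. The scale behind the values is unsettled. They can be intensities scaled up after the scan or powers of another base of log2 summaries. With base e the log2 changes of bright probe sets would be about 0.693 times as large. The factor does not hold for dim probe sets, where the 16 added to each value weighs. The direction is the same under both readings.

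The table held 14010 probe sets, of which 44 are array controls and were left out of the tests. Gene names came from the platform annotation supplied with the values: 12443 probe sets had 1 gene, 327 had several and 1196 had none listed. Of those with 1 gene, 12394 were matched by gene identifier to a current gene table, and 0 symbols had to be updated. The other 49 kept the name of the annotation. No gene was named from a probe set with several. No genome build is named for these values, so no coordinates are given.

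Because trimmed means (116.2 to 148.7) and medians (26.1 to 31.5) differed between arrays, log2 of the value plus 16 was quantile normalized, by a rule set before the data were examined. Probe sets in the lowest 40% of the mean over all 6 arrays were left out, which kept 8379 of 13966. Groups were compared with limma (version 3.58.1 in R 4.3.3; lmFit and eBayes without a trend, two-sided), with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. No rank or permutation test was used for single genes, since 3 against 3 arrays cannot reach an exact p below 0.1. Where all arrays of a group read at or below the highest of 23 negative control probe sets, a change is given as a bound ("at least"), against the higher of the probe set's own value and that control level on each array.

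Gene lists and cell type markers were fixed before the data were examined, 33 in all, of which 32 had at least 5 measured genes. Each gene was taken by its brightest probe set. Lists were tested against all other genes with limma's camera at a preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over the 32 lists. Camera with an estimated correlation and fry, which tests whether the genes of a list move one way on balance without comparing them with other genes, were run beside it. In the lists, older names were updated through the current gene table, 10 names matched no gene, and the cyclophilin Cyp40 was removed from the P450 list, where a name pattern had caught it. One male-biased name resolved to Obp99b, which therefore stands in both sex-biased lists.

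Genes to be named were set before the data were examined. They are tim, per, Clk, vri, Pdp1, cry, Pdf, to, ninaE and w whatever their values; the 10 largest rises and 10 largest falls among genes past the threshold with every tim-MJD array on one side of every wild type array; and up to 3 members of each list past the threshold, largest change first. Other genes are marked as named after their values were seen.

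The procedure was tested on simulated data with the means and spreads of these arrays, 8379 probe sets and 200 changed ones. Of 50 probe sets changed by 0.5 log2 units 32% were recovered, of those changed by 1 log2 unit 62%, by 2 log2 units 82% and by 4 log2 units 100%. Of 156 calls 7.05% fell on unchanged probe sets. A list of cytosolic ribosome genes lowered by 0.5 log2 units was called, and 0 of 31 other lists were. The simulated probe sets varied independently of each other. False calls of lists whose genes are correlated were therefore not tested here.

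Alternatives set beforehand were pseudocounts of 1 and 64, the values as deposited, median centring, cyclic loess, no filter and a filter of 60%, variance trend and robust fits, a plain two-sample test, array weights, other thresholds, replicate number and fluidics module as blocks, and leaving out each array. Natural log values without a pseudocount and covariates for the 3' to 5' difference and for the 18S ribosomal RNA signal were added after seeing the data. The rule that weighs the hemocyte markers was rewritten after their values were seen, and an earlier form of it left that explanation open. Scan day could not be fitted, since each day held 1 group. Figures were drawn with matplotlib 3.10.9 and tables were read with pandas 2.3.3 in Python 3.11.15.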

Results

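Messenger RNA of fruit fly heads was measured on 6 Affymetrix DrosGenome1 arrays, 3 of wild type flies and 3 of flies carrying a tim-GAL4 driver and a UAS-MJD transgene, called tim-MJD here. The labels of wild type 1 and 3 name the strain CS, and that of wild type 2 names none. The driver uses the promoter of the clock gene timeless, and MJD stands for the Machado-Joseph disease protein. The labels of tim-MJD replicates 1 and 2 give a polyglutamine length of 78, and that of replicate 3 gives none. All flies were 2 to 4 days old and were taken at Zeitgeber time 16 after 3 days of light-dark cycles. The sex of the flies is not given in the sources used here. Median intensity per array lay between 26.1 and 31.5. Between 40.2% and 44.4% of probe sets lay above the highest of 23 negative control probe sets on the same array. The number of arrays, 3 per group, limits the precision. The labels do not say whether replicates came from separate fly collections, so p-values of single genes measure the spread between these samples, which can be technical. Camera p-values at the preset correlation weigh the genes of a list against the spread between genes. However small, they do not measure replication between samples. No group with the driver alone or the transgene alone is among these samples, so driver, transgene and genetic background cannot be told apart.

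The one comparison of the design asks which transcripts differed between tim-MJD and wild type heads. In tim-MJD heads the antimicrobial peptide genes Drs and Mtk, the glutathione transferase genes GstE1 and GstD1 and the cytochrome P450 gene Cyp6d2 were higher. The respiratory chain genes COX8 and ND-B14.7 and the odorant binding protein genes Obp19a and Obp56h were lower. Of these, Mtk lost its call with any of 5 arrays left out, COX8 with any of 4 and GstD1 with any of 3. The calls of the others held whichever array was left out. Of 8379 probe sets tested with limma, 208 passed an adjusted p of 0.05, 129 higher and 79 lower in tim-MJD, and 1311 had an unadjusted p under 0.05. The 208 stand for 175 named genes and 30 probe sets without a single gene name. Slob, which encodes a binding partner of a potassium channel, had a probe set in each direction (-0.89 and 1.20) and was named after its values were seen. With the values as deposited, without normalization between arrays, the split was 123 higher and 144 lower. All 208 had every tim-MJD array on one side of every wild type array. Over all tested probe sets 21.9% were separated in this way, where chance gives 10%. The median size of a called change was 2.04 for rises and 1.37 for falls, in log2 units of the deposited values. The log base behind these values is unsettled. If they are powers of e of log2 summaries, log2 changes of bright probe sets are about 0.693 times as large. The rise of Drs would then be about 6.43 in place of 9.28. The factor does not hold where a group lies near control level.

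All wild type arrays were scanned on one day and all tim-MJD arrays on another, so scan day and group cannot be told apart. Fluidics modules 1 and 2 each washed 1 array of each group. With the module as a block, which leaves little replication, 0 probe sets passed in limma and 980 had an unadjusted p under 0.05. RNA quality also differed between arrays. The control probe sets for the 3' end of eIF-4a exceeded those for the 5' end by 9.63 log2 units on wild type 2 and by 2.57 to 3.71 on the others. The middle 18S ribosomal RNA probe set read 12.7 and 12.0 on wild type 1 and 2, and 16.7 to 17.4 on the other arrays. With the 18S signal as a covariate, an alternative chosen after seeing the data, 22 probe sets passed. With the 3' to 5' difference as a covariate 101 passed. Of the 208 calls, 60 held whichever array was left out. Of the gene lists 13 of 32 were called by camera, and 1 with an estimated correlation, which gave the highest adjusted p of 21 alternatives for each of the 13 but the glial one. Calls of probe sets numbered 88 without wild type 1, 117 without wild type 2 and 112 without tim-MJD 3.

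Immune effector genes were higher in tim-MJD heads. Drs, the antifungal peptide drosomycin, went from 8.45 ± 0.48 to 17.73 ± 0.66 (log2 mean ± SD, n = 3), a rise of 9.28 ± 0.41 (SE, adjusted p = 0.00118). BomS4, a short peptide of the Bomanin family, was at the level of the negative controls on all wild type arrays and rose by at least 7.45 (adjusted p = 1.7e-05). Mtk, the antifungal peptide metchnikowin, rose by 5.90 ± 0.92. BomS2 rose by 3.38 and Listericin by 1.60. These 2 were named after their values were seen. Of 21 measured members 5 rose and 16 did not pass, and 12 rose and 1 fell when adjusted over the list alone. The median change of the list was 1.58 (camera, adjusted p = 3.64e-09), and 18 of 21 members were positive. The list lost its call with an estimated correlation (adjusted p = 0.442). Its median was 0.98 without the filter, 1.11 and 1.46 within fluidics modules 1 and 2, and 1.39 with the module as a block. The fat body markers, which stand for a main source of such peptides, had a median of -2.06 (-0.83 without tim-MJD 2), and the hemocyte markers one of -0.06. Mtk lost its call with any of 5 arrays left out (adjusted p up to 0.138, without wild type 1). BomS2 lost it without wild type 1 (0.0528) and Listericin with any of 4 arrays left out (up to 0.0720, without tim-MJD 3).

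**Figure D1:**
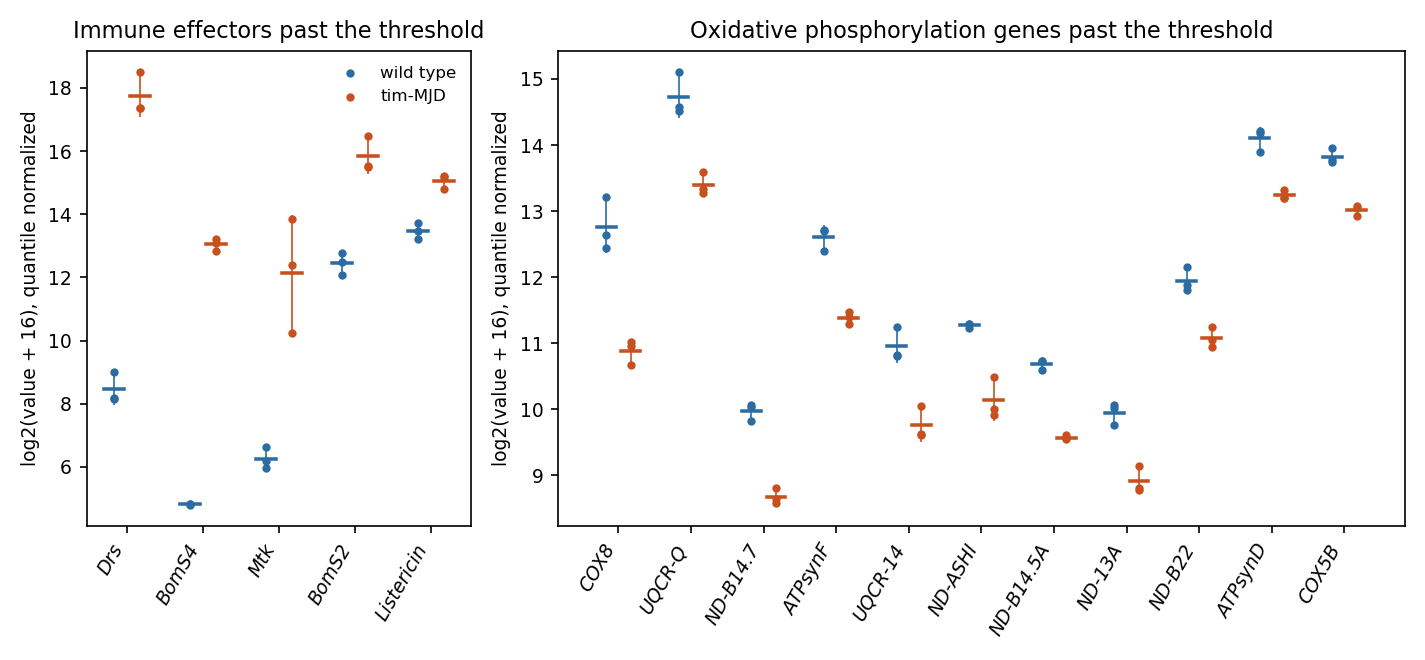
Values of the immune effector genes (left) and oxidative phosphorylation genes (right) that passed the threshold, as log2 of the deposited value plus 16 after quantile normalization. Points are single arrays, horizontal bars are means and vertical lines are 1 SD (n = 3 per group); the tim-MJD arrays lie above all wild type arrays for the 5 immune genes and below them for the 11 oxidative phosphorylation genes.

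Outside the fixed lists, and among probe sets with a single gene name, the largest rises were those of Arc1, a relative of retroviral capsid proteins that carries RNA between cells, and of 5 genes known by number. Arc1 was at control level on all wild type arrays and rose by at least 8.73 (adjusted p = 0.000488). CG15784 rose by 9.12 ± 0.43, CG4757 by 7.39 ± 0.63, CG16772 by 6.73 ± 0.59, CG16978 by 6.12 ± 0.58 and CG4269 by 5.87 ± 0.38. CG15784 and CG4269 were above the negative controls on 2 of 3 wild type arrays and CG4757 on 1 of 3. Without wild type 1, CG16772 (adjusted p = 0.0512) and CG16978 (0.0576) no longer passed. The calls of the others held whichever array was left out.

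Detoxification genes were divided. Among 36 glutathione transferase and redox genes 6 rose and 30 did not pass, and 10 rose and 5 fell when adjusted over the list alone. GstE1 rose by 3.33 ± 0.09 (adjusted p = 0.000321), GstD3 by 3.26 ± 0.42 and GstD1 by 2.39 ± 0.25. The median of the list was 0.09 and its mean 0.44 (camera, adjusted p = 0.0353). The call was lost with an estimated correlation (adjusted p = 0.445) and without wild type 2 (0.0536), wild type 3 (0.189) or tim-MJD 1 (0.0571), as well as with the values as deposited (median 0.03), median centring (0.0059), cyclic loess and the 3' to 5' covariate. The median was 0.06 without the filter, 0.18 with 60% left out and 0.05 with the 18S covariate. It was 0.01 and -0.0037 within modules 1 and 2, and 0.11 with the module as a block. The GstD3 call was lost with any of 5 arrays left out (adjusted p up to 0.0881, without wild type 1) and the GstD1 call with any of 3 (up to 0.0726, without wild type 1). Of 54 cytochrome P450 genes, which oxidise hormones and foreign compounds, 5 rose, 2 fell and 47 did not pass. When adjusted over the list alone 7 rose and 8 fell, and the list as a whole was not called (median -0.03, adjusted p = 0.837). Cyp6d2 rose by 5.84 ± 0.22 (adjusted p = 0.000698), Cyp4p2 by at least 2.63 and Cyp6a20 by 2.60 ± 0.13. Cyp6a23, Cyp309a1, Cyp28d1 and Cyp6a21 were named after their values were seen. The first 3 changed by 2.45, 1.91 and -1.27, and Cyp6a21, at control level on all tim-MJD arrays, by -0.63 or a larger fall. The Cyp4p2 call was lost with any of 4 arrays left out (adjusted p up to 0.102, without wild type 1), that of Cyp28d1 with any of 5 (up to 0.111, without wild type 1) and that of Cyp309a1 without wild type 2 (0.0542). GST and P450 genes have near relatives whose transcripts can bind the same probes.

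Chaperone and proteasome genes were higher as groups, with few single calls. Of 22 heat shock and chaperone genes 2 rose and 20 did not pass, and 7 rose when adjusted over the list alone. The small heat shock protein Hsp26 rose by 2.70 ± 0.35 (adjusted p = 0.0264; above the controls on 2 of 3 wild type arrays) and CCT1, a subunit of the chaperonin that folds actin and tubulin, by 0.90 ± 0.15 (adjusted p = 0.0498). The median of the list was 0.55 (camera, adjusted p = 0.000481). The call was lost with an estimated correlation (adjusted p = 0.506) and with fry. The median was 0.33 without tim-MJD 2. It was 0.45 and 0.81 within modules 1 and 2, and 0.65 with the module as a block. Of 38 proteasome and ubiquitin genes, 0 passed in limma (12 at an unadjusted p under 0.05), and 33 were positive, with a median of 0.38 (camera, adjusted p = 5.7e-06). This call too was lost with an estimated correlation (adjusted p = 0.445) and with fry. When adjusted over the list alone 2 rose and 1 fell. The proteasome median was 0.10 and 0.65 within modules 1 and 2, 0.33 with the module as a block, 0.21 with the values as deposited and 0.19 with median centring. Hsp26 lost its call with any of 4 arrays left out (adjusted p up to 0.0898, without wild type 1) and CCT1 with any of 5 (up to 0.145, without wild type 1). Among 47 autophagy and lysosome genes cathD (1.74 ± 0.18) and CtsB (0.94 ± 0.13), which encode lysosomal proteases, rose and VhaAC45RP, related to a proton pump subunit, fell (-1.56 ± 0.13), while 44 did not pass. When adjusted over the list alone 5 rose and 2 fell, and the list was not called (median -0.01, adjusted p = 0.642). The cathD call was lost without wild type 2 or tim-MJD 3 (adjusted p up to 0.0530, without tim-MJD 3) and the CtsB call with any of 5 arrays left out (up to 0.0888, without wild type 1).

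Oxidative phosphorylation genes were lower in tim-MJD heads. Of 57 measured members 11 fell and 46 did not pass, and 37 fell when adjusted over the list alone. COX8, a subunit of cytochrome c oxidase, fell from 12.76 ± 0.40 to 10.88 ± 0.18 (-1.88 ± 0.22 SE, adjusted p = 0.0210). UQCR-Q, a subunit of complex III, changed by -1.33 ± 0.19 and ND-B14.7, a subunit of complex I, by -1.30 ± 0.10. The median of the list was -0.64 (camera, adjusted p = 5.99e-19), and 51 of 57 members were negative. This was the only one of the 32 tested lists that was also called with an estimated correlation (adjusted p = 0.0248). Its median was -0.71 and -0.56 within modules 1 and 2, and with the module as a block -0.57 (adjusted p = 1.54e-13). COX8 lost its call with any of 4 arrays left out (adjusted p up to 0.0747, without wild type 1) and UQCR-Q with any of 5 (up to 0.110, without tim-MJD 3). Of 33 cytosolic ribosome genes RpL29 fell (-0.76 ± 0.10) and 32 did not pass. That list had a median of -0.15 (camera, adjusted p = 0.00166), with 27 members negative, and lost its call with an estimated correlation (adjusted p = 0.445), cyclic loess, the 18S covariate and fry. Its median was -0.26 and -0.20 within modules 1 and 2, -0.24 with the module as a block, -0.29 with the values as deposited and -0.31 with median centring. When adjusted over the list alone RpL29 was the 1 that fell. The RpL29 call was lost with any of 4 arrays left out (adjusted p up to 0.0858, without wild type 2).

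Of 11 measured core clock genes 0 passed the threshold in limma, and 4 had an unadjusted p under 0.05. The brightest tim probe set read 11.24 ± 0.45 in wild type and 10.25 ± 0.20 in tim-MJD, a difference of -0.99 ± 0.25 (SE, adjusted p = 0.123). A second tim probe set gave 1.23 (adjusted p = 0.276), and the third lay near the negative controls (-0.08), so the probe sets of tim disagree. The blue-light receptor cry differed by 1.20 ± 0.21 (adjusted p = 0.0583), vri by -0.75 (adjusted p = 0.209) and Pdp1 by -0.54 (adjusted p = 0.624). Under 4 of 22 alternatives cry passed: 60% left out (adjusted p = 0.0327), array weights (0.0456), the natural log (0.0492) and, just under the threshold, a pseudocount of 1. Clk (0.26) and per (0.07) lay near control level, where differences are not detectable. The median of the core clock list was 0.07 (camera, adjusted p = 0.766), and 2 rose and 1 fell when adjusted over the list alone. Rhythmic head transcripts, which cycle in fly heads, were lower. Of 22 measured, 5 fell and 17 did not pass, and 10 fell and 1 rose when adjusted over the list alone. Jhbp13 changed by -2.76 ± 0.41, CG10553 by -2.26 ± 0.27 (above the controls on 1 of 3 tim-MJD arrays) and CG14275 by -1.47 ± 0.19. Slob (-0.89) and Cyp6a21 (-0.63 or a larger fall) were the other 2 and were named after their values were seen. The list median was -0.56 (camera, adjusted p = 0.000466), and the call was lost with an estimated correlation (adjusted p = 0.445) and with the 18S covariate (median -0.20). The median was -0.58 and -0.45 within modules 1 and 2, and -0.56 with the module as a block. Jhbp13, CG10553 and CG14275 each lost the call with any of 5 arrays left out (adjusted p up to 0.120, 0.0857 and 0.0865), and this Slob probe set with any of 4 (up to 0.0726, without wild type 1). One time point gives no phase. The neuropeptide Pdf of the clock neurons differed by -0.46 ± 0.11 (adjusted p = 0.111). Of 20 neuropeptide genes AstC, allatostatin C, fell (-1.09 ± 0.15, adjusted p = 0.0300) and 19 did not pass. When adjusted over the list alone 3 fell, and the list was not called (median -0.03, adjusted p = 0.202). AstC lost its call with any of 5 arrays left out (adjusted p up to 0.0968, without wild type 2).

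Markers of the olfactory organ were lower. Obp19a, an odorant binding protein, fell from 9.93 ± 0.38 to 5.38 ± 0.29 (-4.55 ± 0.24 SE, adjusted p = 0.00195; above the controls on 1 of 3 tim-MJD arrays), and the other 11 measured markers did not pass. All 12 were negative, with a median of -1.15 (camera, adjusted p = 3.39e-06), and 7 fell when adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.445). The median was -0.85 and -1.73 within modules 1 and 2, and -1.26 with the module as a block. The co-receptor Orco, shared by many olfactory receptors and named after its value was seen, differed by -0.03 ± 0.12. Outside the list Obp56h changed by -3.10 ± 0.22 and Obp99b by -5.70 ± 0.91 (adjusted p = 0.0478). Obp99b stands among the fat body markers and in both sex-biased lists. It lost its call with any of 4 arrays left out (adjusted p up to 0.143, without wild type 1).

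Fat body markers were lower, most of all on tim-MJD 2. Of 13 measured markers Obp99b fell and 12 did not pass, and it was also the 1 that fell when adjusted over the list alone. The list had a median of -2.06 (camera, adjusted p = 0.00204) and lost its call with an estimated correlation (adjusted p = 0.692). The median was -0.83 without tim-MJD 2. It was -0.67 and -3.80 within modules 1 and 2. The call was also lost with the module as a block (median -2.40, adjusted p = 0.0516), the 18S covariate and fry. The yolk protein transcript Yp2, named after its values were seen, read 10.02 on tim-MJD 2 and 18.36 to 19.72 on the other 5 arrays. Of 6 female-biased fat body genes Cyp4p2 rose and Obp99b fell, as they did when adjusted over the list alone, and the list was not called (median -2.36, adjusted p = 0.346). Its median was -0.58 without tim-MJD 2 and -3.36 and -3.34 without tim-MJD 1 and 3. Within modules 1 and 2 it was -0.55 and -5.98, and with the module as a block -3.27. Only 4 male-biased genes passed the filter, too few for the test. Obp99b fell among them, all 4 fell when adjusted over the list alone, and their median was -2.48, or -1.58 without tim-MJD 2. Without the filter 5 were measured and the male-biased list was called lower (median -2.31, adjusted p = 0.0175), while with 5 measured without wild type 1 or 3 it was not (0.0710 and 0.0642). Of 26 metabolism and fat storage genes Lsd-2, a perilipin of lipid droplets, rose (2.32 ± 0.32, adjusted p = 0.0323) and 25 did not pass, while 2 rose and 6 fell when adjusted over the list alone. That list shares 4 genes with the fat body markers. It had a median of -0.63 (camera, adjusted p = 0.0353) and lost its call without wild type 1 (0.307), wild type 2 (0.0532) or tim-MJD 2 (0.103, median -0.39), with 60% left out, the 18S covariate (median -0.18) or fry, and with an estimated correlation (adjusted p = 0.764). Its median was -0.35 and -0.82 within modules 1 and 2, and -0.50 with the module as a block, where the call was lost too (adjusted p = 0.0516). Lsd-2 lost its call with any of 5 arrays left out (adjusted p up to 0.0986, without tim-MJD 3).

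**Figure D2:**
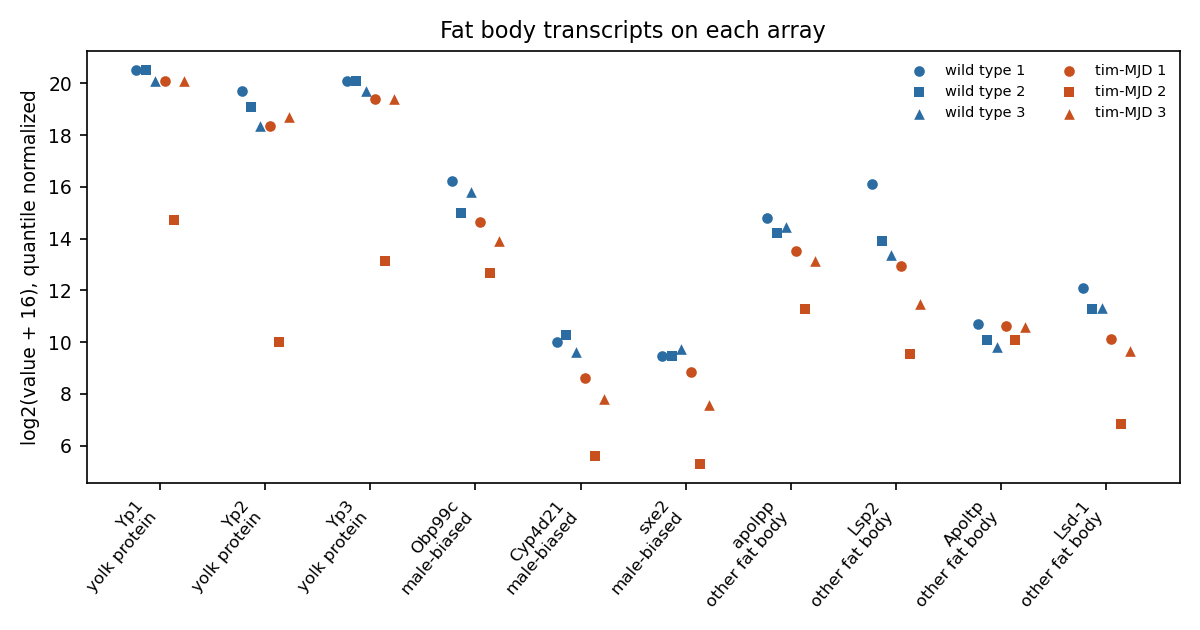
Fat body transcripts on each of the 6 arrays, as log2 of the deposited value plus 16 after quantile normalization, with 1 point per array. Yp2 read 10.02 on tim-MJD 2 and at least 18.36 on every other array, and Apoltp, like Yp2 chosen after its values were seen, lay between 9.82 and 10.71 on all 6.

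Of 7 lysozyme genes 0 passed in limma (6 at an unadjusted p under 0.05), and 5 fell and 1 rose when adjusted over the list alone, with a median of -2.30 (camera, adjusted p = 0.0353). The call was lost without tim-MJD 3 (adjusted p = 0.246), with median centring, the 18S covariate or fry, and with an estimated correlation (adjusted p = 0.689). The median was -1.54 and -1.50 within modules 1 and 2, and -1.64 with the module as a block. Lysozyme genes are near-identical copies and can share probes. Of 15 midgut markers 0 passed in limma (2 at an unadjusted p under 0.05) and 0 when adjusted over the list alone, with a median of -0.81 (camera, adjusted p = 0.0353). Their call was lost without wild type 1 (median -0.44, adjusted p = 0.210), wild type 2 (-0.61, 0.0970), tim-MJD 2 (-0.59, 0.0714) or tim-MJD 3 (-0.52, 0.0942), with median centring, no filter (median -0.03), the 3' to 5' covariate or fry, and with an estimated correlation (adjusted p = 0.764). Without wild type 3 the median was -1.31. As a mean of the list, wild type 3 (-0.73) lay below all tim-MJD arrays (-0.58 to -0.22), and only wild type 1 (1.19) and wild type 2 (0.76) lay above them, the 2 arrays with low 18S signals. The median was -0.84 and -0.01 within modules 1 and 2, -0.27 with the module as a block (not called, adjusted p = 0.172), and 0.30 with the 18S covariate, where the list was called in the other direction (adjusted p = 0.0428). The midgut markers LysB, LysE and LysS, named after their values were seen, are also in the lysozyme list.

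Other large falls, again among probe sets with a single gene name, were those of CG16826 (-8.79 ± 1.33), whe (-8.58 ± 1.23), CG14419 (-3.51 ± 0.53), CG9512 (-3.37 ± 0.11), CG7607 (-2.90 ± 0.33) and Jhbp1 (-2.83 ± 0.41), a member of the juvenile hormone binding protein family. In tim-MJD, CG16826 was above the negative controls on 2 of 3 arrays and whe on 1 of 3, so these sizes are not exact. With the other arrays set to control level they were -8.61 and -7.69. The CG9512 call held whichever array was left out. Those of CG16826, CG14419 and Jhbp1 were lost with any of 5 arrays left out (adjusted p up to 0.123, 0.115 and 0.111), that of whe with any of 4 (up to 0.111, without tim-MJD 3) and that of CG7607 with any of 3 (up to 0.0671, without wild type 2).

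Markers of most other head cells did not pass as groups. Glial markers had a median of -0.23 over 14 genes (camera, adjusted p = 0.0485) and lost their call with an estimated correlation (adjusted p = 0.445). In limma 0 of them passed (5 at an unadjusted p under 0.05), and 2 fell when adjusted over the list alone. The call was also lost without wild type 1 (0.0679), wild type 2 (0.198), tim-MJD 2 (0.111, median -0.11) or tim-MJD 3 (0.0942), with a pseudocount of 1, the natural log, 60% left out, values averaged over the probe sets of a gene or either RNA covariate. The highest adjusted p was 0.576, with the 18S covariate. The glial median was -0.14 with a pseudocount of 64, -0.27 and -0.49 within modules 1 and 2, and -0.39 with the module as a block (not called, adjusted p = 0.134). Neuron markers (median 0.05, adjusted p = 0.583), photoreceptor markers (-0.03, 0.898), hemocyte markers (-0.06, 0.616) and muscle markers (0.10, 0.766) were not called. Neither were those of ovary and eggshell (-0.01, 0.616), testis (0.01, 0.722) and male accessory gland (0.05, 0.616), though the ovary list was called lower with fry (adjusted p = 0.0244). In phototransduction, rdgC, a phosphatase acting on rhodopsin, rose by 1.99 ± 0.30 (adjusted p = 0.0416) and 21 of 22 genes did not pass (median -0.04, adjusted p = 0.898; 2 rose and 1 fell when adjusted over the list alone). The rdgC call was lost with any of the 6 arrays left out (adjusted p up to 0.116, without wild type 2). In monoamine synthesis and transport, speck, an arylalkylamine acetyltransferase, fell (-2.10 ± 0.29) and 7 of 8 genes did not pass (median -0.02, adjusted p = 0.874; 1 rose and 1 fell when adjusted over the list alone). The speck call was lost with any of 5 arrays left out (adjusted p up to 0.106, without wild type 1). The lists for photoreceptor structure and lens (0.02, 0.898), eye pigment (0.03, 0.898), cell death (0.03, 0.898), synapse (-0.01, 0.898) and mating and pheromone (-0.16, 0.158) were not called. When adjusted over the list alone 2 neuron markers and 1 synapse gene rose, and 1 gene each fell of the synapse, photoreceptor structure, muscle and ovary lists. Mean and median had opposite signs for core clock, photoreceptor structure, eye pigment, cell death, autophagy, photoreceptor and hemocyte genes, and the photoreceptor markers were called lower with the 18S covariate (median -0.45, adjusted p = 0.0450). For to, ninaE and w no probe set with a single gene name was given, so they are not analysed here.

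**Figure D3:**
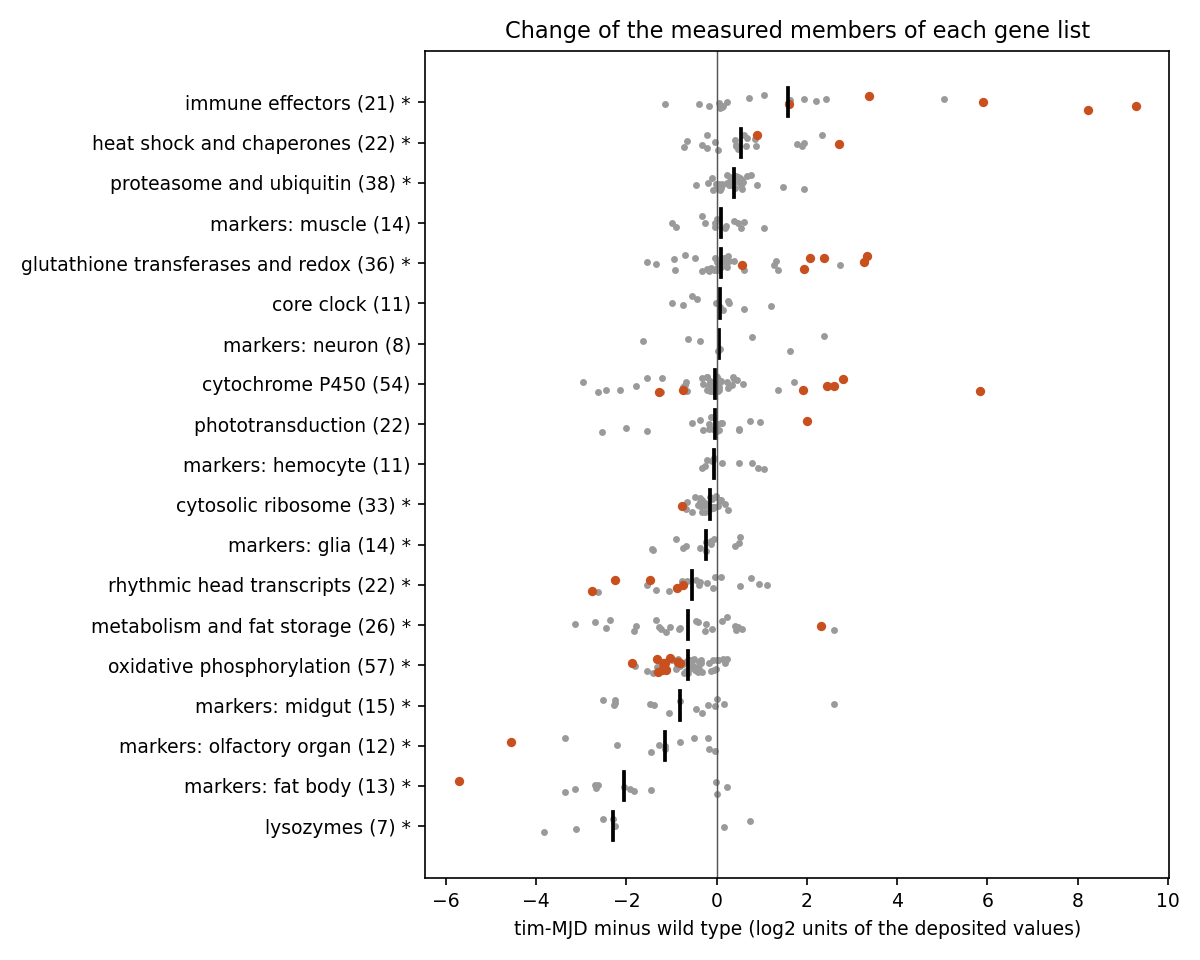
Change of each measured member of 19 gene lists, with tim-MJD minus wild type in log2 units of the deposited values on the horizontal axis. Points are genes, coloured where the gene passed the threshold, black bars are list medians, numbers in brackets are measured genes and asterisks mark lists called by camera; oxidative phosphorylation (median -0.64) alone was also called with an estimated correlation.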

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

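The tests below were chosen after the results they bear on were seen, except the count of gene lists over other splits of the arrays. Fly control probe sets of the array, which enter no comparison, read higher on all tim-MJD arrays than on all wild type arrays for 5 of 12. Actin control probe sets differed by 2.32 (3' end) and 3.37 (middle), 18S ribosomal RNA ones by 2.82 (5' end) and 3.21 (middle) and the GAPDH 3' one by 0.28, in log2 of the deposited value plus 16 without normalization. The middle actin probe set lay below the highest negative control on all wild type arrays. Its 3.37 is therefore not exact, and against the control level the difference is smaller.

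The real split of the 6 arrays gave 208 probe sets and the other 9 splits gave at most 0, so 1 of 10 splits gave as many. For gene lists the real split gave 13 and 1 of 10 splits gave as many, while the highest of the others gave 10. With 10 splits no share under 0.05 can be reached. The split with 10 set wild type 1, wild type 2 and tim-MJD 1 against the others. Each of the other 9 splits mixes the groups and holds part of the real difference, and they called between 1 and 10 lists each. Lists were thus called at the preset correlation under every split. With an estimated correlation the real split called 1 list and every other split 0.

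Immune effectors were higher in tim-MJD by a median of 1.58. Degraded RNA on wild type 2 as the whole cause is argued against, since the median was 1.47 and the list was still called without that array, though with all arrays the call was lost with an estimated correlation (adjusted p = 0.442). More fat body is argued against as well, as far as marker transcripts show tissue amount. Its markers had a median of -2.06 (-0.83 without tim-MJD 2). They share 5 genes with the female-biased and 3 with the male-biased list, so a different sex mix could move this median. Of 4 other markers, apolpp, Lsp2 and Lsd-1 were lower on every tim-MJD array than on every wild type array. Apoltp overlapped between the groups (9.82 to 10.71). These 4 were named after their values were seen. More hemocytes as the whole cause are argued against too, by a rule rewritten after the values were seen. An earlier form of the rule left this explanation open. The 9 hemocyte markers above control level had a median of -0.0562 (SD 0.533), below 1.58 by more than that SD, and the highest differed by 1.05. That SD is a spread between markers and no error of the median. Some markers, such as crq (5.81 in wild type) and srp (5.94), lay near the control level of 5.59 to 5.69. Changes there can read too small, which limits the median as a guide. Hemocytes as part of the cause stay open. Col4a1, vkg, Hml and PPO2, chosen after their values were seen, differed by 1.05, 0.92, 0.78 and 0.51, and the other markers by -0.31 to -0.06. Scan day and genetic background cannot be told apart from the group, since 0 scan days held both groups and no control of the same background was among the samples. Expression of the MJD transgene, and a difference in infection between the fly cultures, stay open and were not tested.

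Oxidative phosphorylation genes were lower by a median of -0.64. RNA degradation as the whole cause is argued against only as far as the eIF-4a and GAPDH control probe sets show it. With their mean 3' to 5' difference as a covariate the median was -0.65 and the list was still called. That covariate mainly sets wild type 2 apart, where the eIF-4a difference was 9.63, against 2.57 to 3.71 on the other arrays. Actin control probe sets were not part of it. A smaller share of fat body stays open: the slope of the list mean on the fat body mean within groups gives a change of 0.078 (95% interval -0.057 to 0.213), where the mean changed by -0.67, but tim-MJD 2 holds 62.1% of the spread behind it and without that array the interval is -0.427 to 0.506. Scan day and genetic background cannot be told apart from the group, since 0 scan days held both groups and no control of the same background was among the samples. An effect of the MJD transgene stays open and was not tested.

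Yolk protein transcripts on tim-MJD 2 lay below the mean of the other tim-MJD arrays, with a median difference of -6.24 over 3 genes. Fewer females alone is argued against, since 3 male-biased genes were also lower there (median -2.61 as read). Of these, Cyp4d21 and sxe2, named after their values were seen, lay at control level on tim-MJD 2, so their falls can be larger. Less fat body alone is argued against, since 4 other fat body markers were lower by a median of only -2.34, and each by less than any yolk protein transcript. Both together may apply, and the medians of the male-biased genes and the other markers would then lie close. They differed by -0.27 as read. The control level limits the male-biased falls, so the true gap is not known, and so few genes do not decide it. Other differences between the flies of this sample were not tested.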

How the results depend on the processing

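The natural log, the 3' to 5' covariate and the 18S covariate were chosen after seeing the data. All 208 called probe sets kept their direction under every alternative run, which their separation between the groups nearly fixes where arrays are left out. Called probe sets (higher, lower) numbered 122 (71, 51) with median centring, 102 (74, 28) without a filter, 387 (218, 169) with 60% left out, 42 (31, 11) with the plain two-sample test, 500 (277, 223) at an adjusted p under 0.1, and 144 were lower with the values as deposited. The filters change how many probe sets are tested. With the fluidics module as a block 0 passed (0, 0), with 1 residual degree of freedom. The 3' to 5' covariate gave 101 (61, 40) and the 18S covariate 22 (15, 7). The 18S signal itself differs between the groups. Leaving out 1 array gave 88 to 200 calls, 56 to 126 higher and 24 to 74 lower, with fewer samples. Called lists numbered 8 with the 18S covariate, 1 with an estimated correlation and 7 with fry. The midgut markers turned from -0.81 to 0.30 with the 18S covariate. Causes not named here were not tested.

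Whether the replicate numbers pair the samples is not settled, and the labels do not say. Deviations of same-numbered arrays correlated at 0.29, 0.05 and 0.30, and those of other pairs at -0.31 to 0.11. Wild type 2 correlated best with tim-MJD 1 (0.11). With the replicate number as a block 84 probe sets passed (49, 35), of which 62 were shared, and the glutathione transferase (adjusted p = 0.0590) and glial lists (0.0862) were not called. Over the named probe sets 747 values under an alternative kept their side of the threshold, 323 lost it and 4, all of cry, gained it. For lists these numbers were 605, 61 and 2, and 1 reversed. Only 40.2% to 44.4% of probe sets per array lay above the highest negative control, and below it changes cannot be measured.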

Other observations

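All tests in this part were chosen after results had been seen. Gene families that share a symbol stem were tested, 86 families with at least 5 measured genes. At the preset correlation 12 were called, 5 higher and 7 lower, and with an estimated correlation 0 were. The 24 odorant binding protein genes (Obp) had a median of -0.68 (camera, adjusted p = 9.34e-05, unadjusted p = 0.0631 with an estimated correlation), and 18 were negative. The 16 that are not olfactory markers had a median of -0.34 (unadjusted p = 0.00568, and 0.0667 with an estimated correlation). The 14 that are in no sex-biased list either had a median of -0.19 (unadjusted p = 0.0455, and 0.101 with an estimated correlation). Imaginal disc growth factors (Idgf), secreted chitinase-like proteins, were higher, with a median of 0.65 over 6 genes (adjusted p = 0.000743, unadjusted p = 0.0159 with an estimated correlation) and 5 of 6 positive. Idgf3 rose by 1.65 and Idgf4 by 1.53, both named after their values were seen, and these calls were lost with any of 4 and any of 2 arrays left out (adjusted p up to 0.0671 and 0.0576, both without wild type 2). Genes of the mitochondrial ribosome were slightly lower, with a median of -0.16 over 42 mRpL genes (adjusted p = 0.000798, unadjusted p = 0.00903 with an estimated correlation) and -0.20 over 20 mRpS genes (adjusted p = 0.0408, unadjusted p = 0.116 with an estimated correlation). With an estimated correlation the adjusted p of camera was 0.582 for Obp, 0.342 for Idgf, 0.336 for mRpL and 0.587 for mRpS. The directions of these 4 families were the same with the values as deposited, with median centring and with cyclic loess. With median centring the Idgf median was 0.42 and the mRpL median -0.26.

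The next 6 genes passed the threshold, stand outside the lists and were chosen after their values were seen. The ferritin subunits Fer1HCH and Fer2LCH, which store iron, rose by 1.47 and 1.60. Transferrin 1 (Tsf1), an iron carrier, rose from 13.96 ± 0.14 to 16.86 ± 0.32 (log2 mean ± SD). The serpin Spn88Ea rose by 3.31, the thioester protein Tep4 by 3.74 and the tetraspanin Tsp42Ed by 4.60. The calls of these 6 genes held whichever array was left out. Their functions were not tested as groups.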
